A study of Homo sapiens with 138 samples.

How the data were processed

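The series measured gene expression by RNA sequencing in 138 samples of frozen human coronary artery. Per the labels' protocols, tissue was ground on dry ice, total RNA was isolated, and ribosomal RNA was depleted before stranded total RNA libraries were made. The submitters' processing notes name bcl2fastq, FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a, Picard, RSEM 1.3.3 and the genome build hg38, without saying which of them made the values. The authors deposited 1 table of 56607 genes by 138 samples. Its name says TPM, but the deposited values are whole-number read counts per gene whose totals differ between samples, so they were treated as raw counts. Of the counts from 1 to 20, 68.66% were even, which leaves open that the mates of a read pair were counted separately; the number of independent fragments may then be lower than the totals. All columns of the table matched a sample.

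Samples were grouped by the source label as explant or normal and by artery segment: LAD (left anterior descending), RCA (right coronary artery) or LCX (left circumflex). The 131 samples with 1 named segment, 102 explants and 29 normals, entered the comparisons between groups; 7 explants with a mixed or unnamed segment did not, but entered the filter, the correlations, the principal components, the checks for outlying samples and 1 alternative. The labels used here do not say whether samples come from separate donors, so p-values measure the spread between these samples. No pair of libraries agreed within sampling noise: the highest correlation of 2 samples' deviations was 0.844, and that pair differed with a chi-square per gene of 216.9. Age, sex, ancestry and clinical data were not used here. Genes on the Y chromosome, XIST and TSIX were left out.

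The design fixed before the data were examined planned limma on log2(TPM + 1). Because the values are counts, the main test was instead the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) with TMM scaling. The planned limma test was not run on TPM, and limma on log2(CPM + 1) was added as an alternative after seeing the data. Genes with a CPM (counts per 1e6 counts) of at least 0.5 in at least 28 samples, 20.3% of all samples, were tested, which left 21824. The planned filter had the same numbers on the TPM scale. One fit with terms for explant or normal and for segment gave explant against normal, RCA against LAD and LCX against LAD; a fit of the 4 LAD and RCA groups gave the interaction. All tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences in spread between samples were tested with a Levene-type test on log2(CPM + 1), comparing absolute deviations with limma 3.58.1 after removal of the means of each kind and segment; the lone normal LCX sample was left out of it.

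The same design fixed 33 gene lists for cell types, pathways and RNA content. They were tested with camera on log2(CPM + 1) with a preset correlation of 0.01 between genes, and again with an estimated correlation. A list score is the mean log2(CPM + 1) of the list's tested members in a sample; scores were compared with a permutation test of 100000 resamples of the explant and normal labels within segment. The smallest p these can give is 1e-05. Pearson and Spearman correlations between scores used all 138 samples and 100000 permutations over a family of 12 relations, and differences of correlations used 10000 permutations.

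Named genes followed a rule of that design, read on CPM in place of TPM. For explant against normal these were the 8 largest differences each way among called genes with a mean CPM of at least 1 in the higher group and a named symbol that is not an immunoglobulin or T cell receptor segment, a mitochondrially encoded gene or a pseudogene. The 2 members with the smallest adjusted p of each called list, 4 coronary disease locus genes and the most abundant member of each list that did not pass were added. The rule for RCA against LAD took the 8 largest each way, and for the other tests 4 each way. Some genes that the rule picks are not reported here. Gene positions come from GENCODE annotation of GRCh38 and are printed only for IDs with the same version as in the table (45220 of 56607 rows).

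Totals ran from 36.4 to 103 M counts per sample (median 68.4 M). PCR duplicates cannot be told from molecules in these counts, so intervals cover counting error and spread only. On simulated counts with 200 of 21824 genes changed, the explant against normal test recovered 55 of 67 genes changed 1.5-fold, 66 of 67 changed 2-fold and 66 of 66 changed 3-fold, with 2 false calls. For 2-fold changes it recovered 196 of 200 in RCA against LAD and 112 of 200 in LCX against LAD. The changed genes were drawn from those with a mean above 200 counts, so these rates do not cover genes of lower counts. The simulated samples shared no structure, whereas random splits of the real samples called up to 1403 genes for explant against normal. The number of false calls may therefore be too low for the real samples. The spread test recovered 0 of 200 genes made 1.6 times as variable in explants, 78 at 2 times and 187 at 3 times; for genes more variable in normals it recovered 52, 166 and 200. The first width tried was 1.6 in explants, and the others were added after it gave no calls. Among unchanged genes its unadjusted p was under 0.05 in 4.75% to 5.36%. Of the genes made 1.6 times as variable in explants, 161 of 200 had an unadjusted p under 0.05, so such differences were lost at the adjustment. Of 400 list scores with no change, the permutation test called 15.

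Alternatives to these choices covered the pseudocount, filter, scaling, samples, covariates and test. DESeq2 1.42.0, limma on log2(CPM + 1), library-size scaling, removal of single doubtful libraries and a composition adjustment were added after seeing the data. The composition adjustment used endothelial, macrophage, fibroblast and adipocyte scores as covariates.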

Results

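RNA was sequenced from explant and normal coronary artery samples. The study set out to map genetic effects on expression in coronary artery over a range of atherosclerosis stages; the labels used here separate explants from normals and name the artery segment. There were 81 explant and 20 normal LAD samples, 16 and 8 RCA samples, 5 and 1 LCX samples, 2 explants of mixed LAD and RCA, and 5 explants with no segment named. Explants had 66.9 ± 8.86 M counts per sample and normals 68.1 ± 7.32 M (SD). Mitochondrially encoded genes took a median of 0.720% of counts in explants and 0.63% in normals, with maxima of 35.2% and 11.3%.

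Explant arteries had lower expression of smooth muscle contractile genes and higher expression of lymphocyte, mast cell, interferon, HLA class II, immediate early and haemoglobin genes than normal arteries. These lists passed camera at its preset correlation, and none of them passed with an estimated correlation. ACTG2, the enteric smooth muscle actin, was 3.66-fold lower in explants (187 ± 159 CPM, SD, n = 102) than in normals (686 ± 1184 CPM, SD, n = 29; adjusted p = 6.46e-11). TPM2, a tropomyosin of the contractile apparatus, was 2.41-fold lower, below the normal median in 99 of 102 explants. HLA-DPA1, an HLA class II chain, was 2.63-fold higher (165 ± 122 against 64.7 ± 58.8 CPM; adjusted p = 4.98e-06). In all, 5306 of 21824 genes (24.31%) passed edgeR's quasi-likelihood test, 3036 higher and 2270 lower in explants; of these, 777 were at least 2-fold higher and fewer were at least 2-fold lower. The share that was higher, 57.22%, was 36.63% with quantile normalization and 76.60% with library-size scaling alone, so the balance of the directions depends on the scaling.

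**Figure D1:**
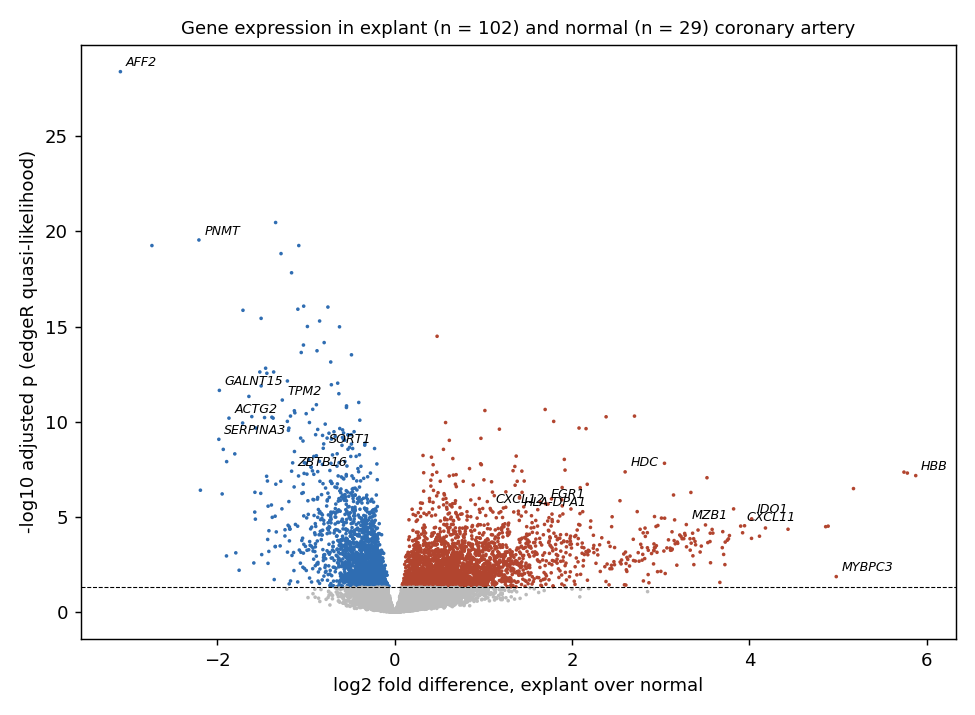
Each point is 1 of 21824 genes, with the log2 difference of explant over normal on the x axis and the negative log10 of the adjusted p on the y axis; red and blue points passed the threshold (dashed line) as higher or lower in explants, grey points did not. The haemoglobin gene HBB lies farthest to the right at a log2 difference of 5.88, and AFF2 farthest to the left at -3.10 with the smallest adjusted p.

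Haemoglobin genes had the largest increases. HBB was 58.8-fold higher in explants (95% interval 18 to 192), with 111 ± 380 CPM in explants and 1.69 ± 3.26 in normals (SD), and lay above the normal median in 99 of 102 explants. A few libraries held much of the explant mean: Explant LAD replicate 57 had 3407 CPM and replicate 68 had 1313. HBA2 and HBA1, which encode the same alpha chain from near-identical copies that short reads hardly tell apart, were 55.1-fold and 53.6-fold higher, and HBD 36.1-fold higher. Normals averaged 0.177 CPM for HBA2, 0.068 for HBA1 and 0.0983 for HBD, so these folds start from very low levels. All 6 tested erythroid genes rose (6 adjusted over the list alone), including ALAS2, the first enzyme of haem synthesis in red cells, at a log2 difference of 3.13 ± 0.63 (SE). The list passed camera at adjusted p = 2.98e-05 (adjusted p = 0.337 with an estimated correlation). Among samples whose study numbers lie within the range of the normals, HBB differed by 3.52 on the log2 scale instead of 5.88. Under the naming rule, which leaves out immunoglobulin segments, the other largest increases were IDO1, a tryptophan-degrading enzyme induced by interferon (16.3-fold), ADAMTS18 (15.4-fold), CXCL11, an interferon-induced chemokine (15-fold), and MYBPC3, cardiac myosin binding protein C. In IDO1 1 library held much of the mean: Explant LAD replicate 47 had 263 CPM and the next explant 24.6, and the fold was not fitted without it. CXCL11 (7.17 ± 44.1 CPM, SD) and ADAMTS18 (2.81 ± 11.1 CPM, SD) also had SDs above their explant means. MYBPC3 rested on 1 library: its log2 difference of 4.98 was 0.47 (adjusted p = 0.307) without Explant LAD replicate 54.

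AFF2, on chromosome X (148500619 to 149000663), had the smallest adjusted p (4.16e-29) and was 8.55-fold lower in explants, with 4.98 ± 4.27 CPM against 43.2 ± 21 in normals. The sex make-up of the groups was not used here. All 102 explants lay below the normal median. PNMT, which methylates noradrenaline to adrenaline, was 4.63-fold lower at low levels (0.476 ± 0.309 against 2.21 ± 1.43 CPM), again in 102 of 102 explants. HS6ST2, a heparan sulfate sulfotransferase, SERPINA3, an acute-phase protease inhibitor, GALNT15, PRODH, a proline dehydrogenase, CILP, a cartilage matrix protein, and RNASE2, an eosinophil ribonuclease, were 3.72-fold to 4.57-fold lower. For CILP (73.1 ± 113 CPM in normals, SD) 45 of 102 explants and for HS6ST2 (1.51 ± 3.14 CPM) 20 of 102 lay above the normal median, so a part of the normals carried these folds. CILP lost its call with a pseudocount of 0.1 in limma (adjusted p = 0.412).

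**Figure D2:**
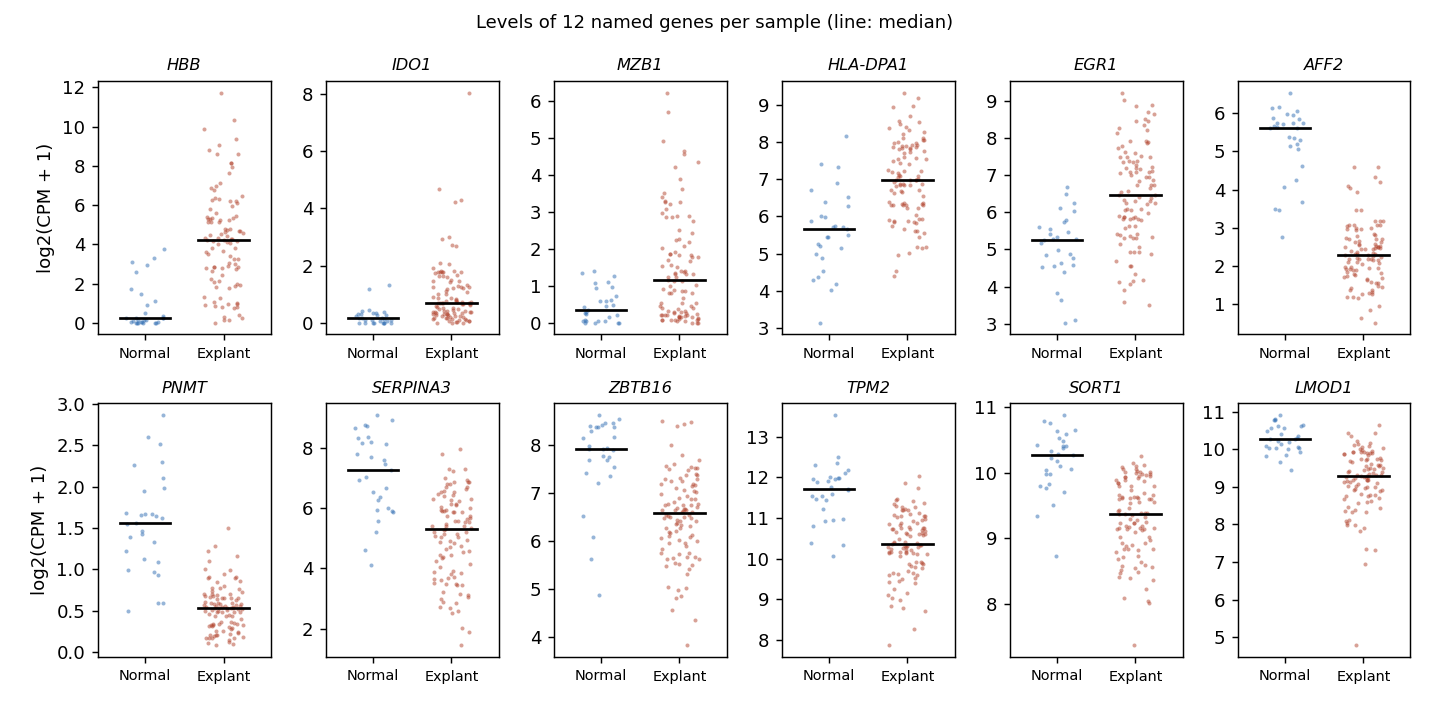
Expression of 12 named genes as log2(CPM + 1) in each of 29 normal and 102 explant samples; points are samples and lines are medians. AFF2 and PNMT lie below the normal median in every explant, while HBB, IDO1 and MZB1 spread upward from low normal levels.

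Of 15 contractile smooth muscle genes, 10 fell, 0 rose and 5 did not pass (12 fell adjusted over the list alone). TPM2, ACTG2, TAGLN (log2 difference -0.76 ± 0.13, SE) and LMOD1, a leiomodin of smooth muscle (-0.93 ± 0.14), were among them, whereas MYH11, the smooth muscle myosin heavy chain, was 4037 ± 1969 CPM in explants and 5121 ± 1803 in normals and did not pass (adjusted p = 0.115; 0.0459 in limma with a pseudocount of 0.1). The camera adjusted p was 5.58e-09 (adjusted p = 0.337 with an estimated correlation). The contractile score differed by -0.63 in explants, below the normal median in 91 of 102 (permutation test, adjusted p = 0.00033). Of 18 extracellular matrix genes, 7 fell and 1 rose (8 and 1 adjusted over the list alone): TNC, the adhesion-modulating glycoprotein tenascin-C, differed by -1.57, ELN, elastin, by -0.90, COL8A1 by -0.77, COL5A2 by -0.53, and THBS2 by 0.40, while COL1A2 did not pass (-0.17 ± 0.13). Its camera adjusted p was 0.000398 (adjusted p = 0.384 with an estimated correlation). The extracellular matrix list lost its call within the study-number range of the normals (adjusted p = 0.141, and 0.2 for its score) and with quantile normalization (adjusted p = 0.0851). The cardiac and vascular patterning list had 3 of 17 members lower, MEIS1, TBX18 and GATA6, transcription factors of heart and vessel development, with 14 not passing, PRRX1 among them (3 lower adjusted over the list alone; camera adjusted p = 0.0335, and adjusted p = 0.384 with an estimated correlation). In LAD samples alone the list lost the camera call (adjusted p = 0.173), and MEIS1 (adjusted p = 0.205) and TBX18 (0.188) lost theirs. The list also lost it with quantile normalization (adjusted p = 0.0851) and with the 4-score composition adjustment (0.112), where TBX18 lost its call too (0.059).

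All 11 tested B and plasma cell genes rose (11 adjusted over the list alone). MZB1, a chaperone of antibody-secreting cells, was 9.78-fold higher and POU2AF1, a B cell transcriptional coactivator, 7.08-fold higher, and the score differed by 1.12 (permutation test, adjusted p = 0.000896). MZB1 had 4.42 ± 10 CPM in explants and 0.462 ± 0.501 in normals (SD). For MZB1 31 of 102 explants lay below the normal median, so a part of the explants carried its fold. For POU2AF1 (2.76 ± 5.85 CPM in explants, SD) 87 of 102 lay above it. Of 14 T cell genes, 13 rose (13 adjusted over the list alone), with CCL5, a chemokine, 2.66-fold and CD247, the T cell receptor zeta chain, 1.89-fold higher; IL7R did not pass (log2 difference 0.46 ± 0.36). Of 8 mast cell genes, 6 rose (6 adjusted over the list alone), HDC, the histamine-forming enzyme, by 6.06-fold and MS4A2, a chain of the IgE receptor, by 2.66-fold. TPSB2, a tryptase with a near-identical neighbour, did not pass (3.13 ± 2.74 against 2.34 ± 3.19 CPM). The camera adjusted p was 8.07e-06 for both lymphocyte lists and 1.09e-05 for mast cells; with an estimated correlation the adjusted p was 0.384 for both lymphocyte lists and 0.337 for mast cells. The macrophage list did not pass camera (adjusted p = 0.150): 3 of 15 members rose and 2 fell (3 and 2 adjusted over the list alone), among them CSF1R, the receptor for macrophage colony-stimulating factor, at 0.64, and CD163, a haemoglobin scavenger receptor, and VSIG4, a complement receptor, fell, at -1.02 and -0.93.

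Of 11 HLA class II genes, 8 rose (9 adjusted over the list alone), with CIITA, their master transactivator, 2.33-fold higher; HLA-DRB1, one of a family of close paralogs, did not pass (1.98-fold, 95% interval 0.907 to 4.33). Of 15 interferon response genes, 14 rose (15 adjusted over the list alone), IFI44L by 2.93-fold and MX1, an antiviral GTPase, by 2.04-fold; IFITM1 did not pass (adjusted p = 0.0923; 0.0451 with DESeq2). Of 18 immediate early genes, 15 rose (18 adjusted over the list alone), EGR1 by 3.25-fold, IER2 by 1.81-fold and FOSB by a log2 difference of 2.93; NR4A1 did not pass. Of 14 inflammatory cytokine genes, 10 rose (11 adjusted over the list alone), including IL1B (3.75-fold), CXCL2 (3.66-fold) and IL6 (2.10 on the log2 scale). Camera adjusted p-values were 2.12e-06 for HLA class II, 5.58e-09 for interferon response, 2.84e-08 for immediate early and 0.000137 for inflammatory cytokine genes; with an estimated correlation the first 3 each had an adjusted p of 0.337 and the cytokines 0.385. In LAD samples alone the cytokine and T cell scores did not pass the permutation test (adjusted p = 0.0885 and 0.149).

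Endothelial genes were higher in 6 of 15 cases (7 adjusted over the list alone), with ERG, an endothelial transcription factor, 1.19-fold and TEK, the angiopoietin receptor, 1.5-fold higher, and VWF, von Willebrand factor, not passing (290 ± 284 against 208 ± 191 CPM). The camera adjusted p was 0.00491 (adjusted p = 0.639 with an estimated correlation), and within the study-number range of the normals neither the list (adjusted p = 0.0752) nor ERG (0.0757) or TEK (0.156) passed. The list also lost its call with adipocyte and cardiomyocyte scores as covariates (adjusted p = 0.0717). Adipocyte genes, markers of perivascular fat, rose in 7 of 13 cases (8 adjusted over the list alone) without a camera call (adjusted p = 0.150), with CIDEA at a log2 difference of 2.61. Of 12 modulated smooth muscle genes, 3 rose and 2 fell (4 and 5 adjusted over the list alone), with VCAM1, a leukocyte adhesion molecule, at 2.16 and FN1, fibronectin, at -0.66; the median log2 difference was -0.08, the mean 0.26, and camera pointed down without a call (adjusted p = 0.847). The signs of median, mean and camera also differed for the cardiomyocyte (3 rose and 1 fell of 9), fibroblast (2 and 1 of 12), nuclear respiratory chain (0 and 1 of 19) and replication-dependent histone (0 and 3 of 9) lists, none of which passed. Members also rose or fell in the heat shock (4 and 1 of 11), cholesterol synthesis (1 and 3 of 13), lipid-laden macrophage (2 and 0 of 17), lymphatic endothelial (2 and 0 of 7), neutrophil (2 and 0 of 7), Schwann cell (2 and 0 of 10), mesothelial (2 and 0 of 6), circadian clock (2 and 0 of 13) and osteochondrogenic (1 and 1 of 13) lists without a camera call. Adjusted over the list alone these counts stayed the same apart from heat shock (5 and 1), Schwann cell (1 and 0) and osteochondrogenic (0 and 0). None of the 13 members of the mitochondrial genome list and none of the 28 cytosolic ribosomal protein genes passed. The 2 mitochondrial ribosomal RNA genes, which are not on that list, were both higher in explants.

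Of 11 glucocorticoid response genes, 7 fell and 1, the phosphatase gene DUSP1, rose (7 and 2 adjusted over the list alone). ZBTB16, a transcription factor that glucocorticoids induce, was 2.24-fold lower in explants, FKBP5, a co-chaperone of the glucocorticoid receptor, differed by -1.35 ± 0.24 (SE), and TSC22D3, a glucocorticoid-induced leucine zipper, was 1.68-fold lower. ERRFI1 did not pass (-0.24 ± 0.14). The camera adjusted p was 0.000398 (adjusted p = 0.337 with an estimated correlation), and the score differed by -0.51 (permutation test, adjusted p = 0.00202). Of 44 coronary disease locus genes, chosen for their nearness to risk variants, 12 fell, 6 rose and 26 did not pass (13 and 7 adjusted over the list alone). SORT1, encoding the sorting receptor sortilin, was 1.75-fold lower and below the normal median in 102 of 102 explants, TNS1, a focal adhesion protein, was 1.76-fold and LMOD1 1.90-fold lower, and CXCL12, a chemokine, was 2.11-fold higher. GUCY1A1, a subunit of the nitric oxide receptor, did not pass (1.14-fold), but did with the 4-score composition adjustment (log2 difference 0.29, adjusted p = 0.0195). Camera gave the list no call (adjusted p = 0.139).

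**Figure D3:**
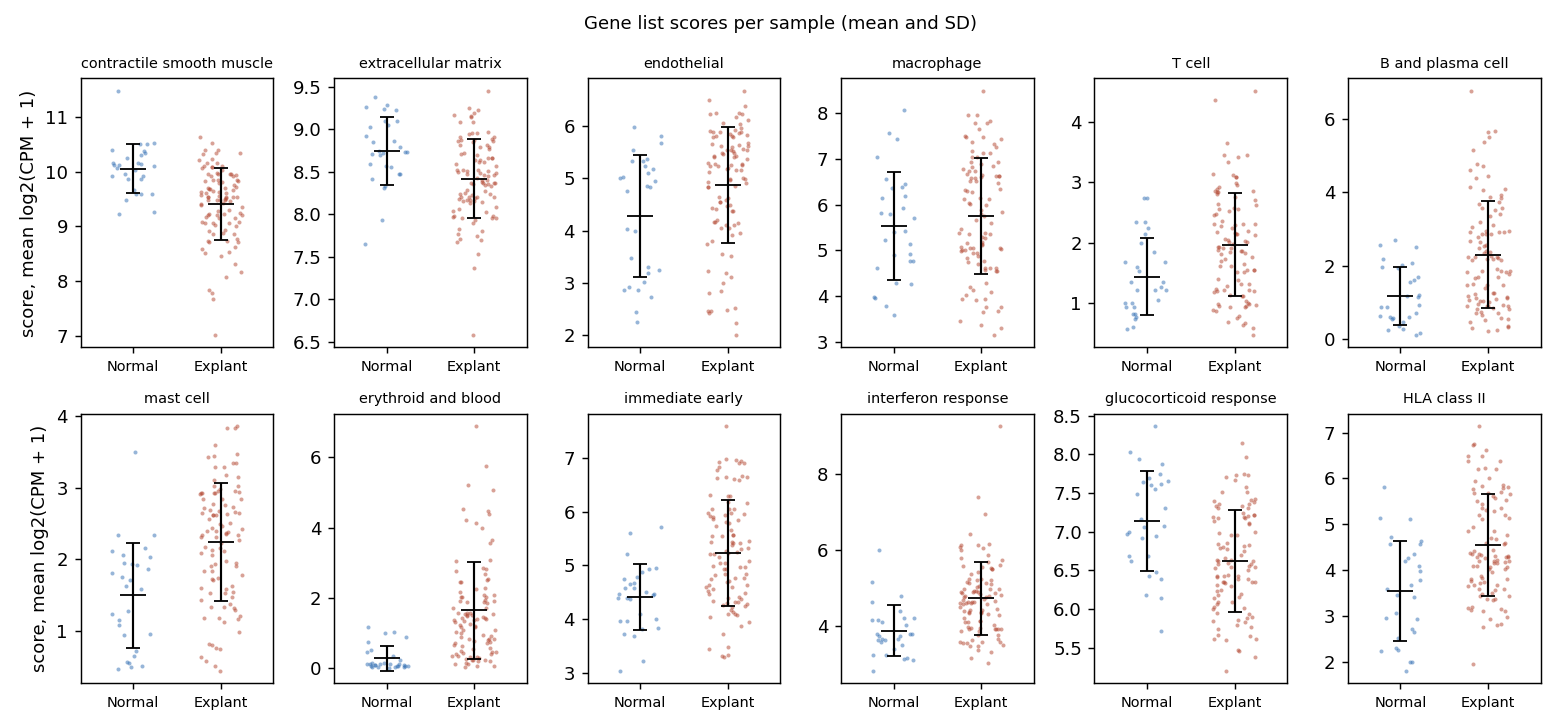
Scores of 12 gene lists, the mean log2(CPM + 1) of each list's members, in 29 normal and 102 explant samples; points are samples, bars are the mean and SD. The contractile and glucocorticoid response scores are lower in explants, the erythroid and HLA class II scores are higher, and the macrophage scores overlap (5.75 ± 1.28 against 5.54 ± 1.18, SD).

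Few genes were called between segments, which does not show that expression was equal, least of all for the 6 LCX samples. In RCA against LAD, 1 gene passed edgeR's test (1466 at an unadjusted p under 0.05, 1 with DESeq2, a different gene, and 0 with limma), the immunoglobulin delta chain gene IGHD. It fell outside the naming rule and was named after its values were seen: it was 7.78-fold higher on average, but 13 of 24 RCA samples lay above the LAD median (6.52 ± 30.1 against 0.706 ± 1.58 CPM), so few samples carried it. No gene list member passed over all genes; adjusted over the list alone, 7 of 10 Schwann cell and nerve genes were lower in RCA (median log2 difference -1.61), as was 1 mesothelial gene, and of the coronary disease locus genes 1 was higher and 2 lower. Camera passed 10 lists, 5 up and 5 down (adjusted p from 1.22e-07 to 0.0384), with the mitochondrial genome, lipid-laden macrophage, macrophage, modulated smooth muscle and T cell lists up in RCA and the Schwann cell, mesothelial, fibroblast, cholesterol synthesis and immediate early lists down; with an estimated correlation the smallest adjusted p was 0.519. The T cell list lost its call with a pseudocount of 0.1 (adjusted p = 0.0661) and the immediate early list in explants alone (adjusted p = 0.364). For the mitochondrial genome list, Explant RCA replicate 12 (13.7% mitochondrial counts) and Normal RCA replicate 7 (11.3%) lay far above their group medians (0.781% and 0.631%). On the other side, so did Explant LAD replicate 74 (35.2%). The RCA lists were not tested without these libraries. Median, mean and camera differed in sign for the contractile, osteochondrogenic, neutrophil, adipocyte, cardiomyocyte, heat shock, inflammatory cytokine, interferon and nuclear respiratory chain lists, none of which passed. In LCX against LAD, 3 genes passed (1740 at an unadjusted p under 0.05; 1 with DESeq2 and 1 with limma), all but RN7SL3 named after their values were seen. RN7SL3, a signal recognition particle RNA, and IGHJ3 were higher, each above the LAD median in 3 of 6 LCX samples, and AC127496.7 was lower in 6 of 6. Without Explant LCX replicate 1, 0 genes passed, and without Explant LCX replicate 5, 468 did. For the interaction, whether the explant difference is larger in RCA than in LAD, 0 genes passed edgeR's test, 727 had an unadjusted p under 0.05, and 0 passed with DESeq2 or limma.

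Explants varied more than normals in HBA1, HBA2, MZB1 and CTSG, and less in CILP, CYP4B1 and AOX1, but most of these calls depended on the settings. The spread test called 67 genes, 38 more variable in explants and 29 in normals (3324 at an unadjusted p under 0.05). The balance depended on the setting: it was 3 against 26 with adipocyte and cardiomyocyte scores as covariates and 36 against 7 within the study-number range of the normals. HBA2 had an SD of 1.80 in explants and 0.342 in normals on the log2(CPM + 1) scale (adjusted p = 0.00155), HBA1 1.37 and 0.159, MZB1 1.43 and 0.450, and CTSG, a protease of mast cells and neutrophils, 1.15 and 0.634. Normals averaged 0.177 CPM for HBA2, 0.068 for HBA1 and 0.462 for MZB1. Values this low vary little once 1 is added before the log, so these wider spreads may partly restate the higher levels in explants. CILP had an SD of 2.05 in explants and 3.08 in normals (adjusted p = 0.0403), CYP4B1 1.5 and 2.42, and AOX1, aldehyde oxidase, 1.14 and 1.87. With a pseudocount of 0.1 HBA1 kept its call and HBA2 (adjusted p = 0.0671), MZB1 (0.236), CTSG (0.624), CILP (0.185), CYP4B1 (0.285) and AOX1 (0.0587) lost theirs. With adipocyte and cardiomyocyte scores as covariates HBA2 (0.335), HBA1 (0.413), MZB1 (0.107) and CTSG (0.307) lost theirs, and within the study-number range of the normals MZB1, CILP, CYP4B1 and AOX1 did. With a pseudocount of 0.1 the count of genes was 10, and with as many explants as normals it was a median of 11.5 over 20 draws (0 to 222).

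Within explants, samples with lower contractile scores had higher macrophage scores (Pearson r = -0.56, Spearman rho = -0.57, permutation p = 1e-05 for each, the smallest the permutations can give; adjusted p = 2.4e-05 and 1.71e-05 over 12 relations), and r was -0.61 without the 2 samples farthest from the median. In normals r was -0.12 (rho = -0.14, n = 29, adjusted p = 0.53). The contractile and adipocyte scores also went opposite ways in explants (r = -0.41, rho = -0.49, adjusted p = 6.86e-05; r = -0.40 without 2 samples) and not in normals (r = 0.15, rho = 0.29, adjusted p = 0.461). The macrophage score went with the B and plasma cell score (r = 0.75 in explants, 0.80 in normals) and with the osteochondrogenic and calcification score (r = 0.84 and 0.80), with an adjusted p of 2.4e-05 for each. The contractile and cardiomyocyte scores correlated with r = 0.24 and rho = 0.76 in explants and r = 0.75 in normals. Without the 2 samples farthest from the median r was 0.81 in explants, so the lower r rests on those samples. The cardiomyocyte score averaged 9 of 16 listed genes, and MYH7, MYH6, MYL2, TNNI3 and NPPA lay under the filter. Normal LAD replicate 7 had a cardiomyocyte score of 6.999 (mean of normals 5.87 ± 0.402, SD) with MYH7 at 0.0511 CPM. A high score therefore need not mean heart muscle in the sample. The relation of contractile and matrix scores did not pass (r = 0.15 in explants, adjusted p = 0.142; r = 0.34 in normals, adjusted p = 0.101), and in all explants r was 0.07 without 2 samples. In LAD explants alone r was 0.26 (adjusted p = 0.0308) with a rho of 0.14. In LAD explants alone the contractile and cardiomyocyte relation had r = 0.10 (adjusted p = 0.372) and rho = 0.76, so there too only r was low. Sequencing batch was not used here. The study number in the titles correlated with the first 2 principal components at r = 0.23 and 0.37.

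**Figure D4:**
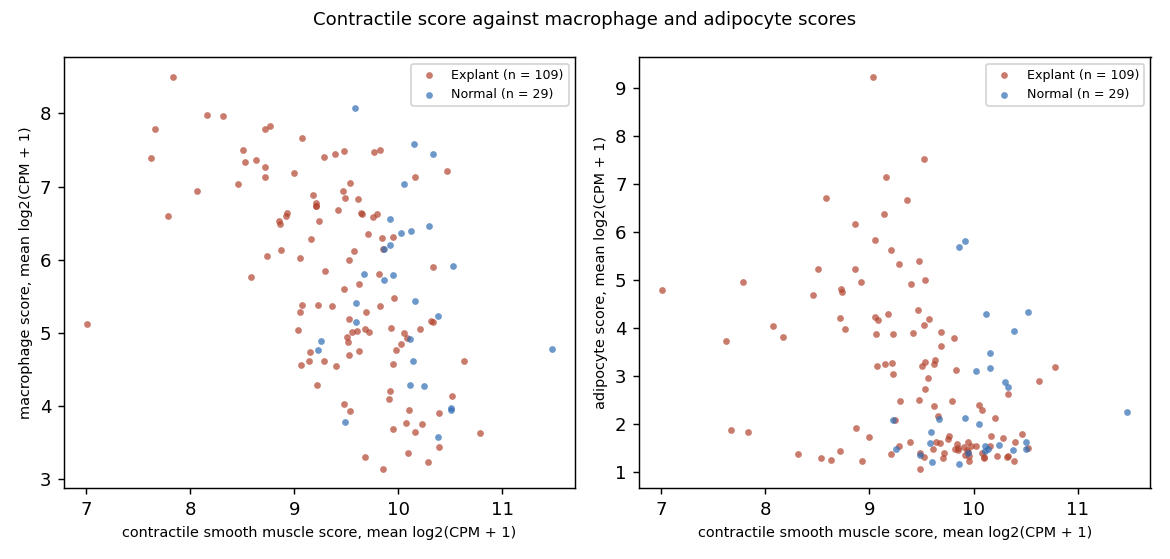
Contractile smooth muscle score (x axis) against macrophage score (left) and adipocyte score (right), both as mean log2(CPM + 1); each point is 1 explant or normal sample. The macrophage score declines with the contractile score in explants (r = -0.56) and the adipocyte score does so less closely (r = -0.41).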

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

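The tests of study number, muscle share, library content, composition and glucocorticoid exposure were chosen after the results were seen. The platelet test and the splits of the samples were written down before their results were seen. Explant LAD replicate 54 carried transcripts of ventricular muscle that lie under the filter: MYH7 at 53598 CPM against at most 28.2 in any normal, MYL2 at 10361 against 3.55, TNNI3 at 6016 against 1.89, MYH6 at 571 against 7.65 and NPPA at 18.7 against 0.373. These are genes the comparisons did not use. In 48 checks of small groups 4 samples lay far from the others, where chance alone flags about 1 in 20: Normal RCA replicate 7 with 11.3% mitochondrial counts (next highest 0.901%), Normal RCA replicate 8 with an erythroid score of 1.03 (next 0.476), Normal RCA replicate 6 with an inflammatory cytokine score of 1.40 (next 2.32), and Explant unspecified replicate 2 with a T cell score of 0.518 (next 2.54). The correlation of contractile with macrophage scores differed between explants and normals by -0.44 (permutation p = 0.0147, adjusted p = 0.0441 over 6 differences), and that of contractile with adipocyte scores by -0.56 (permutation p = 3e-04, adjusted p = 0.0018); in LAD samples alone both differences missed the threshold (adjusted p = 0.414 and 0.0822).

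Contractile genes were lower while lymphocyte and mast cell genes were higher in explants. A lower share of smooth muscle alone would raise the markers of all other cell types alike. The B and plasma cell score rose more than the macrophage score by 0.863 (permutation p = 6e-05). This pair was picked after both scores had been compared, so the p restates their unequal rises and is no independent test of a lower share. Library depth and RNA content were tested next: with total counts, mitochondrial and RN7SL percent as covariates the contractile difference was still -0.618 ± 0.133 (SE). Within the study numbers shared by both kinds the difference was -0.6 (permutation p = 2e-05, 34 explants and 29 normals). The wider range of study numbers in explants is therefore not the whole cause. Whether these numbers follow collection order is not known here, so that order stays open. Disease in the explants was not tested and stays open as a cause, as do a lower share of smooth muscle and a different mix of immune cells.

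Haemoglobin transcripts were higher in explants. The wider range of study numbers in explants does not account for all of it. Within the shared study numbers the erythroid score still differed by 0.843 (permutation p = 1e-05, the smallest possible), although the HBB difference was smaller there. It is not known here whether study numbers follow collection order. Blood left in the tissue could contribute, since a platelet score rose by 0.0598 (permutation p = 0.0389). Unlike the other scores, it averaged all 8 listed genes, those under the filter included. None of the 3 platelet genes that passed the filter was called, and a score this small leaves the share of blood open. Within the 102 explants the erythroid score went with the platelet score (r = 0.55, rho = 0.54; r = 0.52 without the 2 samples farthest from the median) and with the neutrophil score (r = 0.55, rho = 0.65; r = 0.58 without 2), each with an adjusted p of 1e-05 over 2 relations chosen after the result was seen, the smallest possible. Differences in how the tissue was rinsed or stored before freezing were not given in the labels used here and were not tested.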

How the results depend on the processing

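Tests with DESeq2, limma on log2(CPM + 1), library-size scaling, left-out doubtful libraries and the 4-score composition adjustment were chosen after seeing the data. The explant against normal count of 5306 stayed within 1.5 times under 19 of 22 alternatives (4091 to 7233; 5228 with limma on log2(CPM + 1), 5759 with DESeq2, 5013 without 3 libraries over 10% mitochondrial and 5733 without the library with myocardial transcripts). It was 3312 in LAD samples, 93 in RCA samples and a median of 3505 over draws with as many explants as normals (2633 to 7053), where fewer samples entered. With study number as a covariate it was 4091, of which 3647 were called the same way in the main test. A stable count did not mean the same genes. Of the 5306, 3884 were called the same way with quantile normalization and 3805 within the study-number range of the normals. That number was 4205 with the 4-score composition adjustment, 5205 with DESeq2 and 5237 with median-ratio scaling.
The RCA against LAD count of 1 was 0 with limma at a pseudocount of 1 or of 0.1, so the pseudocount itself moved nothing. It was also 0 with a CPM of at least 1 in 69 samples, with study number and with adipocyte and cardiomyocyte scores. Quantile normalization and sample weights, both in limma, gave 0 as well. The count was 474 with no filter, 5 in explants and 2 in normals. The LCX count of 3 was 1 with limma at a pseudocount of 1 or of 0.1 and with DESeq2, and 0 with quantile normalization in limma. Leaving out 1 LCX sample at a time gave 0 to 468. The interaction stayed at 0 under 7 alternatives. The spread count of 67 was 10 with a pseudocount of 0.1, 43 within the study-number range, 29 with adipocyte and cardiomyocyte scores and a median of 11.5 with as many explants as normals. With an estimated correlation 0 of the 13 explant lists and 0 of the 10 RCA lists passed; the 14 list scores past the permutation test became 9 in LAD samples.
Reversed directions: COL1A2 was 0.00629 within the study-number range; with the 4-score adjustment MYBPC3 was -0.21, IL7R -0.0791 and VWF -0.41 (adjusted p = 0.0221), and the endothelial list changed direction (adjusted p = 0.966), where the endothelial score is itself a covariate; without 1 LCX sample at a time the gene RN7SL3, LCX vs LAD, ran from -0.27 to 2.698 and IGHJ3 from -2.32 to 4.29, with both reversals without Explant LCX replicate 1, while AC127496.7 kept its direction but lost its call in 4 of 6 such fits and with quantile normalization (adjusted p = 0.203); the contractile and adipocyte correlation in normals was -0.00391 in LAD samples, and the explant minus normal difference of the contractile and cardiomyocyte correlations was 0.079 without the library with myocardial transcripts. Where no cause is named, the cause was not tested. Among named genes 486 values kept direction and call, 37 were weaker and 3 stronger.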

Other observations

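The tests in this part on glucocorticoid-related genes were chosen after the results were seen. Beyond the fixed lists, several genes with the smallest adjusted p, named here after their values were seen, were lower in explants: TCEAL4 at -1.34 ± 0.10 (SE, log2), MSRB1, a selenoprotein reductase, at -1.08 ± 0.09, and TXNRD1, thioredoxin reductase, at -0.80 ± 0.08, while NR3C1, the glucocorticoid receptor, was higher at 0.48 ± 0.05 (adjusted p = 3.26e-15). Of the hypoxia response list, 5 members rose and 2 fell of 11 tested (6 and 2 adjusted over the list alone), with VEGFA at 1.16 and ADM, adrenomedullin, at 1.52; the list did not pass camera (adjusted p = 0.145), though its score was higher in explants by 0.227 (permutation test, adjusted p = 0.0279), a call it lost in LAD samples alone (0.177, adjusted p = 0.198).

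A hypothesis is that the normal arteries had seen more glucocorticoid hormone, as their higher ZBTB16, FKBP5 and TSC22D3 would go with. A second list of 12 genes that glucocorticoids induce, sharing none with the first, was tested: its score was lower in explants by -0.387 (permutation p = 0.00042), with 6 members lower, 1 higher (ANGPTL4) and 5 not passing. Among them HIF3A differed by -1.65 ± 0.19, GPX3 by -1.20 ± 0.15 and MAOA, monoamine oxidase A, by -1.06 ± 0.14. This second list was chosen after the results were seen, in the same samples, so its p is no independent test of the hypothesis. With endothelial, macrophage, fibroblast and adipocyte scores as covariates the first list's score still differed by -0.671 ± 0.112 (SE). The contractile, lymphocyte and mast cell scores, which differed between the kinds, were not covariates, so cell composition stays open. Within the shared study numbers the difference was -0.413 (permutation p = 0.018), so the wider range of study numbers in explants is not the whole cause. Whether study numbers follow collection order is not known here. These genes also answer to other signals, and drug treatment before sampling was not used here, so the exposure may differ or the response may; the data do not separate them.

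Whether other groupings of the samples give as many genes was tested with 100 splits, the real one included. For explant against normal, 1 of 100 splits within segment, the real one, gave as many genes as the real 5306, and the highest other gave 1403. A share of 1 of 100 is the smallest that 100 splits can give, so a random split is unlikely to reach that count. That a random split can call 1403 points to structure among the samples. For the spread test 1 of 100 gave as many as 67 (highest other 24), again the smallest share possible, though the count of 67 itself changed with the settings. For RCA against LAD 87 of 100 splits gave at least the real 1 gene (highest other 1441), and for LCX against LAD 51 of 100 gave at least 3 (highest other 3012), so chance is not excluded for either. For the interaction the real count was 0, which all 100 reach by construction (highest other 90), so its splits test nothing. The first principal component held 34% of the variance and went with the neutrophil (r = 0.90) and macrophage (r = 0.89) scores; the second held 11.7% and went with the adipocyte (r = 0.79) and Schwann cell (r = 0.75) scores.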
